A study of Drosophila melanogaster with 6 samples.

How the data were processed

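Whole Drosophila melanogaster larvae in the middle of the second instar, about 36 hours after hatching, were assayed on 6 Affymetrix arrays, 1 per pool of larvae. Wild-type pools came from the strain w1118 and mutant pools were err1/err2 larvae, which carry a pair of different mutant alleles of the ERR gene (estrogen-related receptor, a nuclear receptor). Each genotype had 3 pools. Per the labels, the pools were separate collections, mutant larvae were picked under a fluorescence microscope from a cross of balanced parents, and larvae were chosen by hand for size, vitality and spiracle form. Groups and replicate numbers were taken from the sample labels.

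The deposited values are MAS5 signals, an intensity on a linear scale with 1 value per probe set, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version is not given in the sources used here, and detection calls were not used here. The deposited intensity table held 18952 probe sets. The mean signal of each array after removal of 2% of the values at each end was 500.0, and these means spanned a 1.00-fold range, so no further scaling was applied. This scaling fixes the mean of each array, so that a change shared by most transcripts is not visible. Array medians ran from 83.1 to 110, and all 3 mutant medians lay above all 3 wild-type medians.

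After 183 control probe sets were left out, 18769 remained. Values were taken as log2(signal + 9.35), the pseudocount being 0.1 of the median of all values (93.5). A fold on this scale understates the change of a dim gene and depends on the pseudocount where a group lies near the bottom of the range. Probe sets whose mean log2 value over the 6 arrays lay at or above the 40th percentile were tested, which left 11261, with a threshold near a signal of 44.5. Differences are the mutant mean minus the wild-type mean, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with genotype as the only term and two-sided Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Adjusted p-values below come from limma unless another test is named. The number of arrays limits the precision. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

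Of the 18769 probe sets, 13647 had 1 gene symbol in the platform table, 402 had several and 4720 had none. Of those with 1 symbol, 13544 matched the RefSeq gene table of the Release 6 assembly through the Entrez identifier, and this table was used for names and for the order of neighbouring genes. The symbols named 11982 genes, of which 8885 were tested. Genes were represented by their brightest probe set in the gene lists. Among 583 genes with several tested probe sets, 3 had probe sets more than 2 log2 units apart and 1 had calls in opposite directions.

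Before the data were examined, 26 gene lists, the design, the rule for naming genes and the alternatives were fixed. Of 600 list members, 488 were matched, 107 were not named here, 5 were left out because their names conflicted, and 450 were tested. Among the members not analysed here are lactate dehydrogenase and pyruvate kinase. The lists for glycolysis, lactate, the pentose phosphate pathway and carbohydrate digestion were chosen knowing that ERR has been tied to carbohydrate metabolism in larvae, so they are not independent evidence of a direction. Each list was counted for called members and, with at least 5 measured genes, tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over 25 lists. Named genes are ERR, the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap and whose higher mean lies above that group's median, every measured gene of the glycolysis, lactate and pentose phosphate lists, and up to 4 called members of each other list with the smallest adjusted p, or the brightest member where none was called. Genes named outside this rule are marked as chosen after their values were seen. The Osiris and Tweedle families were added as lists after the largest rises had been seen, and 60 families of genes that share a symbol prefix were then tested.

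The alternatives were quantile normalization, alignment of array medians, pseudocounts of 1 and of 0.5 times the median, no filter, a filter at the 60th percentile, no intensity trend, a robust variance prior, array weights, a replicate block, leaving out each array, a fold of at least 1.5, an adjusted p under 0.01, the mean of all probe sets of a gene, and the list tests named above. A fit with the mean log2 value of 12 Osiris genes as a covariate was added after the data were seen.

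The limma and camera steps were tested on simulated data for the comparison of 3 mutant with 3 wild-type arrays over 11261 probe sets, drawn from the real means and moderated spreads. With 200 changed probe sets, 88.3% of shifts of 2 log2 units, 50.0% of shifts of 1 unit and 5.63% of shifts of 0.5 units were called, every call had the right sign, and 5 of 11061 unchanged probe sets were called. In 100 simulations with 1 shifted list of 12 genes among 20 lists, camera called the shifted list each time and called 9 of 1900 unshifted lists. Genes were independent in those simulations, which real lists are not. Only 200 probe sets were changed there, while 1834 were called in the real data. An adjusted p depends on how many probe sets change, so these shares do not tell what share of real shifts was called.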

Results

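Transcript levels were compared between err1/err2 mutant and wild-type whole larvae at the middle of the second instar, with 3 arrays per genotype, to ask which genes differ when the nuclear receptor ERR is mutated. Errors on signals are SD with n = 3, and differences are log2 values, mutant minus wild type, with their standard error (SE). Spearman correlations ran from 0.944 to 0.951 between wild-type arrays, from 0.934 to 0.946 between mutant arrays and from 0.910 to 0.941 across genotypes. Mutant array 2 lay farthest from the wild type, and the SD of its log2 difference from mutant array 1 was 0.67, against 0.40 to 0.42 for pairs of wild-type arrays. The first principal component held 62.1% of the variance and separated the genotypes.

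The ERR transcript itself, measured by 1 probe set, had a signal of 105 ± 14.1 in wild type and 114 ± 38.1 in mutants. The difference of 0.07 (SE 0.28 without the low-value filter, adjusted p = 0.922) was smaller than the spread between arrays, and its sign turned under other settings, such as -0.10 with quantile normalization. Mutant arrays 1, 2 and 3 read 100.1, 157.5 and 85.3. Where this probe set lies relative to the lesions of the alleles is not given in the sources used here, so the level does not check the genotype labels.

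Of 11261 tested probe sets, 1834 (16.3%) differed between the genotypes, 1007 higher and 827 lower in mutants. They stood for 1578 distinct named genes, with 214 probe sets that have no gene or several. Large changes were mostly rises: of 597 probe sets that differed at least 2-fold, 414 rose and 183 fell, and of 197 that differed at least 4-fold, 161 rose and 36 fell. The arrays of the genotypes did not overlap for 4134 probe sets (36.7%), where chance gives 10% for a single probe set. Probe sets of an array move together, and all mutant medians lay above all wild-type medians. The share without a genotype difference could therefore lie far from 10%. The median difference of all tested probe sets was 0.04 as deposited, -0.06 after quantile normalization and -0.17 after alignment of array medians, and the share of calls that rose went from 54.9% to 45.3% and 29.5%, so small differences are read relative to that shift. The count fell to 1036, 1045 and 1130 without wild-type arrays 1, 2 and 3.

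Genes of sugar breakdown fell together. In glycolysis, which splits glucose into pyruvate, 9 of 10 measured genes fell and none rose. Pfk, the phosphofructokinase that commits sugar to the pathway, went from 5081 ± 510 to 543 ± 51.7 (-3.20, SE 0.11, adjusted p = 3.42e-06), and Pgi, the isomerase before it, from 11337 ± 889 to 1478 ± 62.9 (-2.93, SE 0.09, adjusted p = 2.59e-06). Pgk (-2.02), Tpi (-1.94), Gapdh1 (-1.49), Eno (-1.37), Hex-A (-0.84), Ald1 (-0.72) and Pglym78 (-0.41) also fell. Hex-C, a hexokinase, was at 898 ± 169 in wild type and 875 ± 57.6 in mutants (-0.02, adjusted p = 0.934). The mean difference of the list was -1.50 (camera adjusted p = 2.43e-11, adjusted p = 0.166 with an estimated correlation), and 9 genes fell when adjusted over the list alone. Pglym78 was no longer called without any 1 of 5 arrays, all except mutant array 2. This list was chosen with ERR's tie to carbohydrate metabolism in mind and is not independent evidence of its direction.

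**Figure D1:**
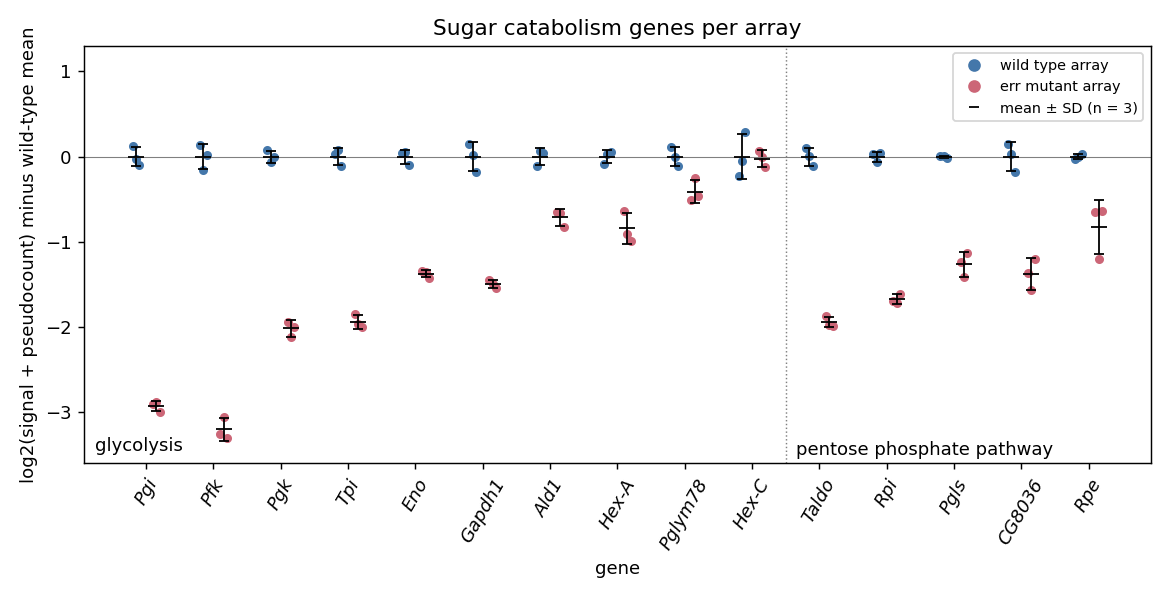
Log2 (signal + pseudocount) of the measured glycolysis and pentose phosphate genes on each array, relative to the wild-type mean of the gene, with mean and SD over 3 arrays. Mutant arrays lie below all wild-type arrays for every gene shown except Hex-C, with the largest falls at Pfk (-3.20) and Pgi (-2.93).

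All 5 measured genes of the pentose phosphate pathway, which makes NADPH and ribose from glucose, also fell, and the same count fell when adjusted over the list alone. The dehydrogenases Zw and Pgd, which make the NADPH, were not named on the array, so those steps were not analysed. CG5103 lay below the low-value filter. Taldo (transaldolase) went from 13427 ± 977 to 3473 ± 145 (-1.95, SE 0.09, adjusted p = 1.3e-05), Rpi, the ribose phosphate isomerase, fell by 1.68, and CG8036 (-1.38), Pgls (-1.26) and Rpe (-0.83) fell too. The mean was -1.42 (camera adjusted p = 4.04e-07, adjusted p = 0.166 with an estimated correlation). Only Gpdh1, a glycerol phosphate dehydrogenase, passed the low-value filter in the list of the lactate and glycerol phosphate shuttle. Gpo3, Gpdh2 and Gpdh3 lay below it, and the list was too small for a list test. By the brightest of its 4 probe sets, Gpdh1 fell from 19748 ± 2127 to 10724 ± 782 (-0.88, SE 0.11, adjusted p = 0.00151). With 1 gene, adjustment over the list alone changes nothing. Both lists carry the same caution as glycolysis about how they were chosen.

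In the list for trehalose and glycogen, the circulating sugar and the storage polymer, 7 of 14 measured genes fell, none rose and 7 were not called. Adjusted over the list alone, 7 fell and 1 rose. Pgm1, the phosphoglucomutase that joins glycogen to glycolysis, fell by 2.20 (SE 0.10, adjusted p = 1.3e-05), as did CG9485, a glycogen debranching enzyme (-2.48), the glycogen synthase Glys (-1.44) and the glycogen phosphorylase Glyp (-1.15). The mean was -0.65 (camera adjusted p = 0.000683, adjusted p = 0.208 with an estimated correlation).

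Sugar-digesting genes moved the other way. In the carbohydrate digestion list, 8 of 11 measured genes rose, none fell and 3 were not called, with 9 up and 1 down when adjusted over the list alone. The maltases Mal-A7, Mal-A8, Mal-A6 and Mal-A4 rose by 4.13 (SE 0.19), 2.85 (SE 0.16), 2.72 (SE 0.17) and 1.40 (SE 0.11), with adjusted p from 1.3e-05 to 0.000166. Mal-A7 went from 69.8 ± 19.6 to 1344 ± 29.5. The list mean was 1.37 (camera adjusted p = 3.05e-06, adjusted p = 0.166 with an estimated correlation). This list too was chosen knowing of ERR's tie to carbohydrate metabolism.

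In the list for pyruvate dehydrogenase and the TCA cycle, which burns pyruvate, 4 of 16 genes fell, 1 rose and 11 were not called, with equal counts when adjusted over the list alone. Of its 23 members 17 were named on the array. Pdha, Pdhb, kdn, SdhA, Fum1 and Mdh2 were not, so these enzymes were not analysed. Mdh1, the malate dehydrogenase of the cytosol, fell from 14631 ± 1055 to 8244 ± 398 (-0.83, SE 0.09), as did ScsbetaG (-0.53) and Idh3g (-0.45), while Ogdh, the oxoglutarate dehydrogenase, rose by 0.59. Idh3g lost its call without any 1 wild-type array, and Ogdh after alignment of array medians (0.39). In the respiratory chain and ATP synthase list, 7 of 50 genes fell, none rose and 43 were not called, and 6 fell when adjusted over the list alone. The complex I subunits ND-13A (-0.60), ND-B14 (-0.49), ND-B14.5B (-0.48) and ND-B18 (-0.46) fell, ND-B14 not without any 1 wild-type array, and 45 of the 50 differences were negative. The list means were -0.20 (camera adjusted p = 0.00573, and p = 0.669 adjusted with an estimated correlation) and -0.18 (camera adjusted p = 3.17e-06, and p = 0.669 adjusted with an estimated correlation). After quantile normalization the means were -0.09 and -0.06 and both list calls ended (camera adjusted p = 0.568 and 0.435), while alignment of array medians gave 8 and 17 genes that fell. The TCA count was 2 without wild-type array 1 or 2, and the respiratory chain count was 3 without any 1 wild-type array and 4 without mutant array 3.

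In the list of cytochrome P450 and glutathione transferases, enzymes that modify foreign compounds and hormones, 17 of 48 measured genes rose, 3 fell and 28 were not called, with 23 up and 4 down when adjusted over the list alone. Cyp6a17 went from 29.3 ± 3.48 to 1888 ± 24.3 (5.62, SE 0.13, adjusted p = 5.31e-07), Cyp6a8 rose by 4.75, Cyp9c1 by 3.09 and GstE9 by 1.80. The mean was 0.67 (camera adjusted p = 0.000456, adjusted p = 0.166 with an estimated correlation). Among families of shared symbol prefix, tested after the data were seen, all 67 measured Cyp genes did not pass (18 rose, 5 fell, camera adjusted p = 0.0661), nor did the 12 GstE genes, of which 4 rose and 4 fell (mean -0.057, camera adjusted p = 0.878), or the 11 GstD genes, of which 4 rose and 0 fell (mean 0.44, camera adjusted p = 0.0871).

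**Figure D2:**
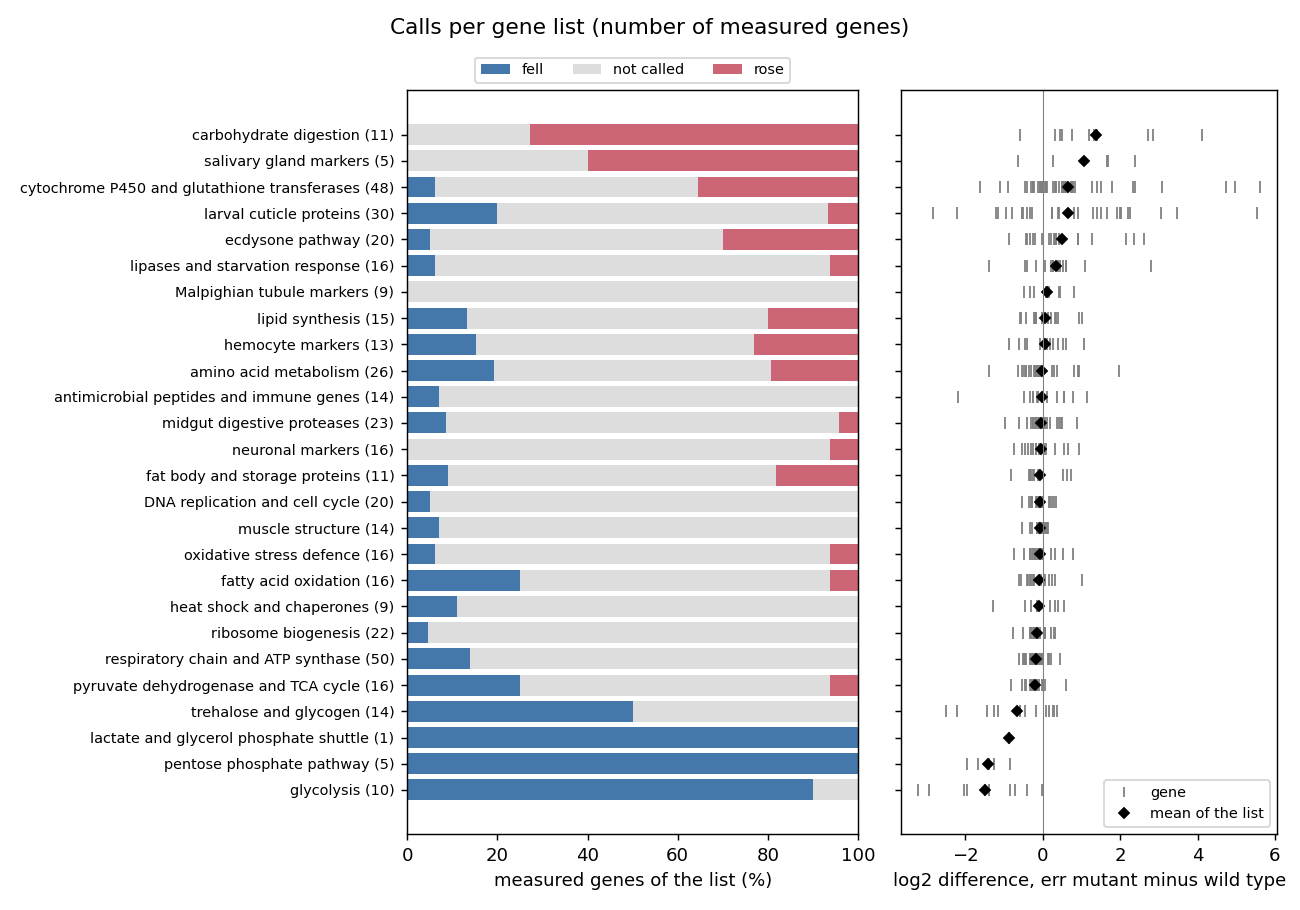
Left, share of the measured genes of each fixed list that fell, were not called or rose (measured genes in brackets). Right, log2 difference of each measured gene, mutant minus wild type, and the mean of the list as a diamond. Glycolysis (mean -1.50) and carbohydrate digestion (mean 1.37) lie at opposite ends.

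The largest rises were led by Osiris genes, a family of insect membrane proteins expressed in tissues that make cuticle. Osi6 went from 28.2 ± 24.7 to 10935 ± 4873 (8.35, SE 0.52, adjusted p = 5.28e-05) and Osi15 from 35.4 ± 29.1 to 7647 ± 4055 (7.51, SE 0.62). Osi20, Osi9 and Osi19 rose by 6.27, 5.90 and 5.81, and CG13135, CG7406, CG3355, CG14107 and CG1304 by 7.78, 6.58, 6.39, 5.86 and 5.78. A second probe set of CG13135 differed by 0.11. Wild-type signals of these genes lay at the bottom of the range, so the size of each rise depends on the pseudocount. Of 12 tested Osiris genes, a family looked at as a whole after these rises were seen, 9 rose and 3 were not called, with a mean of 4.44 (camera adjusted over the pair of added families, adjusted p = 2.13e-08, adjusted p = 0.124 with an estimated correlation) and 10 up when adjusted over the list alone. Without the low-value filter, which left out genes dim on average over all arrays, 11 of 23 rose, 12 were not called and the mean was 2.63. The mean log2 level of the 12 tested genes was 8.84, 10.77 and 9.97 on mutant arrays 1, 2 and 3 and 5.10, 5.77 and 5.38 on wild-type arrays 1, 2 and 3. With this level as a covariate, chosen after the data were seen, 22 probe sets were called in place of 1834, and 93.4% of its variance lay between the genotypes. Glycolysis then kept 2 calls, with a mean of -1.40, and no gene was called in the pentose phosphate, trehalose and glycogen or carbohydrate digestion lists. Their means were still -1.0, -0.55 and 1.89, and calls ended with an SE that grew 3.90-fold in the median over all probe sets.

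**Figure D3:**
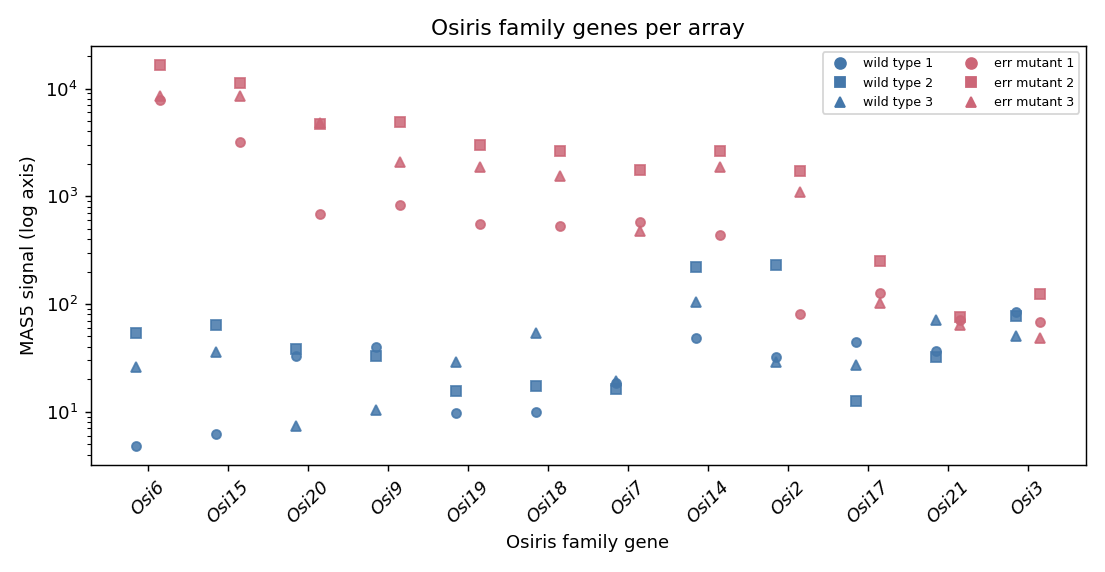
MAS5 signal on a log axis for the 12 tested Osiris genes on each of the 6 arrays, ordered by log2 difference, with 1 marker shape per replicate number. Osi6 was at 4.8 to 54.1 in wild type and at 7796 to 16549 in mutants.

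The largest falls included Alp8 and Alp7, alkaline phosphatases. Alp8 went from 4068 ± 753 to 4.57 ± 1.42 (-8.18, SE 0.18, adjusted p = 5.31e-07) and Alp7 from 1414 ± 130 to 41.7 ± 19.3 (-4.88, SE 0.29). CG32444 (-5.20), CG8160 (-4.36), the sorbitol dehydrogenase Sodh1 (-3.29), CG10474 (-3.22), the cuticle protein Cpr97Eb (-2.84) and CG33225 (-2.76) fell as well. Pfk and Pgi, described above, complete the 10 largest falls.

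Lists of hormone response and cuticle moved in part. In the ecdysone pathway, the response to the moulting hormone, 6 of 20 genes rose, 1 fell and 13 were not called, with 6 up and 2 down when adjusted over the list alone. ImpE3 and ImpE1, which respond to ecdysone, rose by 2.61 (SE 0.44) and 2.36 (SE 0.41), Eip78C by 1.28 and Cyp18a1, which inactivates ecdysone, by 0.92. The list did not pass (mean 0.49, camera adjusted p = 0.312). Among 30 larval cuticle proteins, 2 rose, 6 fell and 22 were not called, with 7 up and 7 down when adjusted over the list alone. Cpr47Eb rose by 1.51, and Cpr97Eb (-2.84), Lcp65Ac (-1.21) and Lcp65Aa (-0.95) fell. Their mean (0.66, from 0.218 to 1.27 when 1 array was left out) and median (0.42) were positive while the test pointed down (camera adjusted p = 0.898).

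Lists of lipid use, starvation and amino acids held calls in both directions and did not pass camera. In fatty acid oxidation, 4 of 16 fell and 1 rose (2 up and 5 down when adjusted over the list alone, mean -0.08, camera adjusted p = 0.204): whd, the carnitine palmitoyltransferase, rose by 1.03, and Echs1 (-0.55), Acadvl (-0.40) and colt (-0.38) fell. Acadvl and colt lost their calls without any 1 wild-type array and without mutant array 3, and colt also without mutant array 2. In lipid synthesis, 3 of 15 rose and 2 fell (4 up and 3 down when adjusted over the list alone, mean 0.07, median -0.01, camera adjusted p = 0.994). SCAP, which escorts the transcription factor SREBP, rose by 1.03 and Agpat2 by 0.94. In contrast mdy, which makes triglyceride, and Lsd-2, a lipid droplet protein, fell (-0.59 and -0.55), Lsd-2 not without wild-type array 1 or 3. The list of lipases and starvation response passed with fry (adjusted p = 0.0116), but not after alignment of array medians (fry adjusted p = 0.304). In it, 1 of 16 rose and 1 fell (4 up and 1 down when adjusted over the list alone, mean 0.34, camera adjusted p = 0.296). The former was tobi, a glycosidase and not a lipase, from 115 ± 29.4 to 850 ± 198 (2.79, SE 0.23), and the latter mag, a gut lipase (-1.39, SE 0.14). In amino acid metabolism, 5 of 26 rose and 5 fell (6 up and 5 down when adjusted over the list alone, mean -0.02, camera adjusted p = 0.312), among them Got1, an aspartate aminotransferase, which fell by 1.38, and Prat2, hgo and P5CS, which rose by 1.98, 0.94 and 0.82.

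Tissue markers were measured to see whether the makeup of the larvae moved with genotype. Of 5 salivary gland markers 3 rose, also when adjusted over the list alone: ng1, ng2 and ng3, glue-related genes, by 2.37 (SE 0.17), 1.70 (SE 0.18) and 1.67 (SE 0.27). Their mean was 1.08 (camera adjusted p = 0.0141, adjusted p = 0.208 with an estimated correlation), and the call ended without the low-value filter (camera adjusted p = 0.0676), where 3 of 11 rose, 8 were not called, the mean was 0.60 and the median 0.20. The 6 Sgs glue genes of this list lay below the filter. No other tissue list passed. Of 13 hemocyte markers 3 rose and 2 fell (3 up and 4 down when adjusted over the list alone, mean 0.06, camera adjusted p = 0.994): PPO1, a prophenoloxidase, rose by 1.07 and He by 0.60, and the collagens vkg (-0.85) and Col4a1 (-0.61) fell. He lost its call without any 1 wild-type array. Of 11 fat body and storage genes 2 rose and 1 fell (2 up and 5 down when adjusted over the list alone, mean -0.05, camera adjusted p = 0.273), Tsf1 and Idgf3 by 0.72 and 0.52 and fon at -0.32. When each of the 6 arrays was left out in turn, Tsf1 lost its call in 3 fits and Idgf3 and fon in 5 each. Of 14 muscle genes 1 fell (mean -0.07, median -0.01, camera adjusted p = 0.465), Act87E (-0.54, not called after quantile normalization or without mutant array 3 or wild-type array 1 or 3), and of 16 neuronal genes 1 rose (mean -0.04, camera adjusted p = 0.603), Rbp9 by 0.94. Counts were equal when adjusted over the list alone. Of 9 Malpighian tubule markers limma called 0, also when adjusted over the list alone, with 3 at an unadjusted p under 0.05 (mean 0.11, camera adjusted p = 0.684), and the brightest, Cyp12e1, read 1060 ± 195 and 1118 ± 61.4.

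The remaining lists did not pass and held few calls, equal in number when adjusted over the list alone. Of 23 midgut proteases 1 rose and 2 fell (mean -0.03, camera adjusted p = 0.465): Ser6 by 0.89, and Jon65Aii and zetaTry at -0.98 and -0.62. Jon65Aii lost its call without any 1 wild-type array, and Ser6 without wild-type array 1 or 3. Of 14 immune genes 1 fell (mean -0.02, camera adjusted p = 0.829), PGRP-SC2, an amidase that breaks down peptidoglycan, from 6787 ± 499 to 1488 ± 221 (-2.19, SE 0.12). Of 9 heat shock genes Hsp68 fell by 1.28 (mean -0.10, camera adjusted p = 0.592). Of 22 ribosome biogenesis genes Nop10 fell by 0.77 (mean -0.15, camera adjusted p = 0.182), and of 20 replication and cell cycle genes PCNA fell by 0.53 (mean -0.06, camera adjusted p = 0.428). Of 16 oxidative stress genes Cat (catalase) rose by 0.79 and MtnA, a metallothionein, fell by 0.74 (mean -0.08, camera adjusted p = 0.264). Across the 25 lists tested, 8 passed with the preset correlation, 7 with fry and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Other splits of the arrays gave up to 10 lists past camera with the preset correlation. Each of them mixes the genotypes unevenly and keeps part of their difference, so these counts do not tell how many lists would pass without one. The p values rose with an estimated correlation even where that estimate lay below the preset 0.01. For salivary gland markers it was -0.086, and the unadjusted camera p went from 0.0045 to 0.044. The loss of all lists is thus not a measure of correlation alone, and how far the preset p values overstate the evidence is not known. The lists are therefore read from their single-gene calls.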

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

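The Osiris covariate was chosen after the data were seen, and the other alternatives before. Of 97 named genes other than ERR, 81 kept their direction and their side of the threshold under every alternative scaling, pseudocount, filter, variance prior, weighting, replicate block and left-out array in which they were tested, and 91 of the 97 were tested with the filter at the 60th percentile. Glycolysis, the pentose phosphate pathway, trehalose and glycogen, carbohydrate digestion, and the P450 and transferase list passed camera with the preset correlation under every scaling, pseudocount, filter, variance prior, weighting, replicate block and left-out array, with glycolysis means from -1.70 to -1.44. With an estimated correlation 0 of 25 lists passed, at the same means of -1.50, -1.42, -0.65, 1.37 and 0.67 for these lists and -0.20, -0.18 and 1.08 for the TCA cycle, respiratory chain and salivary lists. Fry did not call the TCA cycle (-0.20) or the respiratory chain (-0.18), and called lipases and starvation response (0.34), which camera did not. Quantile normalization gave the same fry calls for these lists. After alignment of array medians fry called the TCA cycle and the respiratory chain (adjusted p = 0.0422 and 0.0336) and not lipases and starvation response (adjusted p = 0.304). Dim genes limit precision, since no detection calls were used, and array number limits all results. Candidate causes are weighed below for the fall of sugar genes, the rise of Osiris genes and the share of calls. The cause of other changes was not tested.

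Adjusted p under 0.01 left 787 probe sets, 428 higher and 359 lower, and a fold of at least 1.5 left 497 lower. Aligned array medians gave 537 higher and 1283 lower, and 8 and 17 falls in the TCA cycle and respiratory chain. Of the 1834 calls, 1349 were shared with that setting and 1524 with quantile normalization. Without 1 array the counts ran from 1036 to 1860 in all, 586 to 996 higher, 449 to 864 lower, 2 to 5 falls in the TCA cycle, 3 to 6 in the respiratory chain and 33 to 53 among mitochondrial ribosomal proteins. Respiratory chain falls numbered 4 without the intensity trend. With the replicate block 1379 probe sets were called, 1330 of them among the 1834, and 4 respiratory chain genes fell. The numbers did not pair the arrays: same-numbered arrays had correlations of their deviations of -0.07, 0.17 and -0.13, and 2 of 6 arrays matched their own number best.

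The ERR difference was -0.10 with quantile normalization, -0.14 with aligned medians, -0.044 with array weights and -0.17 to 0.24 without 1 array. With quantile normalization the means were -0.086 for the TCA cycle, -0.062 for the respiratory chain, 0.073 for midgut proteases, 0.073 for muscle and -0.014 for Malpighian tubule markers. With aligned medians they were -0.14 for lipid synthesis, -0.15 for hemocytes and -0.093 for Malpighian tubule markers, and Cyp12e1 was at -0.12. Without a filter they were 0.023 for fat body and 0.60 for salivary glands. Array weights gave 0.028 for amino acid metabolism and 0.031 for midgut proteases. Without 1 array, means ran from -0.069 to 0.036 for amino acid metabolism, -0.20 to 0.39 for immune genes, -0.17 to 0.017 for fat body, -0.11 to 0.077 for midgut proteases, -0.13 to 0.036 for neuronal markers and -0.28 to 0.060 for ribosome biogenesis, and differences from -0.14 to 0.12 for Hex-C and -0.051 to 0.22 for Cyp12e1.

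With the Osiris covariate 22 probe sets were called, 6 higher and 16 lower, 12 of them among the 1834. Glycolysis kept 2 falls and 2 genes of the P450 list rose in this fit. In the pentose phosphate, trehalose and glycogen, TCA cycle, respiratory chain, carbohydrate digestion, salivary, mitochondrial ribosomal and Osiris lists 0 genes were called in the direction counted before. The covariate nearly repeats genotype, and standard errors grew 3.90-fold in the median. ERR was at -1.09. Signs turned for Hex-C (0.044), Rpe (0.20), Idh3g (0.050), whd (-0.033), Echs1 (0.043), colt (0.098), Jon65Aii (0.69), ImpE1 (-0.40), Cyp18a1 (-0.083), Act87E (0.011), Col4a1 (0.024) and He (-0.22). They also turned for the means of the TCA cycle (0.096), respiratory chain (0.0038), fatty acid oxidation (0.25), amino acid metabolism (0.53), midgut proteases (0.58), heat shock (0.36), ecdysone pathway (-0.39), larval cuticle (-4.02), muscle (0.19), neuronal (0.11), hemocyte (-0.16), Malpighian tubule (-0.054), ribosome biogenesis (0.86) and oxidative stress (0.24) lists.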

Other observations

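Genes of the mitochondrial ribosome, which makes the proteins encoded by mitochondrial DNA, fell together in mutants. Of 69 measured genes 52 fell, 1 rose and 16 were not called, with a mean difference of -0.51. Of its genes, mRpL12 and mRpS16 are named after their values were seen. mRpL12 went from signals of 3760 to 3914 on the wild-type arrays to 1941 to 2387 on the mutant arrays (-0.80, SE 0.10, adjusted p = 0.00169), and mRpS16 was at -0.70 (SE 0.13). The count was 53 after quantile normalization and 61 after alignment of array medians, and it fell to 33 without wild-type array 1. Of 39 genes of the cytoplasmic ribosome limma called 0, with 3 at an unadjusted p under 0.05 and a mean of -0.12, and 1 and 3 fell under those scalings. Of their differences 34 were negative and this list passed camera in the same direction (adjusted p = 0.00876, over 3 lists picked after the data were seen). It did not pass after quantile normalization (camera adjusted p = 0.714) or with an estimated correlation (camera adjusted p = 0.509). The mitochondrial group was picked from 60 families of shared symbol prefix, of which 6 passed camera: mRpL, mRpS, Osi, Mal, ND and Alp, with adjusted p from 2.54e-20 to 0.0153. The RpL and RpS families of the cytoplasmic ribosome did not pass there (camera adjusted p = 0.188 and 0.291). None of the 60 passed with an estimated correlation (adjusted p = 0.733 for each of the 6).

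Some other genes are named here after their values were seen. The zona pellucida proteins dyl and neo rose by 5.0 (SE 0.56, adjusted p = 0.00104) and 3.83 (SE 0.36, adjusted p = 0.000484), and ImpL1, which responds to ecdysone, by 4.97 (SE 0.23, adjusted p = 1.3e-05), each higher on all 3 mutant arrays than on any wild-type array. Of 21 Tweedle cuticle genes 2 rose and 4 fell, with a mean of 1.80 that did not pass (camera adjusted p = 0.189). The probe sets of RFeSP differed by 0.21 and 5.54, those of smp-30 by -2.14 and 0.24, and those of PMCA ran from -0.43 to 0.99 with calls in both directions.

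The predictions for scaling, moult phase, a single array, larval stage and strain background were written after the results were seen, and those for genes near ERR and for other splits before. The other scalings and the left-out arrays themselves were fixed before the data were seen, and the Osiris level was chosen after. For the fall of sugar genes, the tables argue against the scaling of the arrays as the cause, since the glycolysis mean was -1.44 or lower under both other scalings. The values argue against a moult phase in proportion to the Osiris level as the whole source of the fall of the glycolysis genes. Their mean log2 value was 11.001, 10.977 and 10.881 on mutant arrays 1, 2 and 3, whose Osiris levels were 8.84, 10.77 and 9.97. Within genotypes it changed by -0.021 per unit of that level (95% interval -0.13 to 0.093), against -0.34 per unit between genotypes. With the level in the fit the mean difference went from -1.50 to -1.40 (95% interval -1.93 to -0.88, 3 residual degrees of freedom). That interval takes the Osiris level as measured without error and its relation as a straight line. Wild-type Osiris levels lay near the bottom of the range, so the slope rests mostly on the 3 mutant arrays. Single-gene calls went from 9 to 2 because the level nearly repeats genotype, with the median SE going from 0.10 to 0.40, so the count of calls does not decide. For the pentose phosphate genes the mean went from -1.42 to -1.0, with an interval of -1.91 to -0.090 that lies below 0 but leaves room for a large part to follow that level. A moult phase that lowers these genes without following the Osiris level cannot be told apart from genotype. An effect of the ERR mutation itself stays open as a hypothesis.

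For the rise of the Osiris genes, a single array does not account for it, since at least 9 Osiris genes rose without any 1 mutant array. That outcome was in part fixed in advance, since the family was picked from largest rises that all mutant arrays had to share. Mutant larvae may have been nearer to a moult than wild-type larvae of the same age. That candidate explanation cannot be told apart from an effect of genotype on these genes, because 93.4% of the variance of the Osiris level lay between genotypes and no separate measure of stage was used here. In the ecdysone pathway list 6 of 20 genes rose, ImpE3 (2.61) and ImpE1 (2.36) among them, and 1 fell. Of 30 larval cuticle genes 2 rose and 6 fell, with 7 up and 7 down when adjusted over the list alone. Of their differences 18 were positive and 12 negative, with a mean of 0.66. Of 21 Tweedle genes, in part the same genes, 2 rose and 4 fell, with 16 differences positive and 5 negative. The cuticle genes therefore do not point in 1 direction. Per the labels larvae were chosen by hand for size, vitality and spiracle form, which gives no value of stage per array.

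For the large share of calls, variants carried along with the err alleles were tested through the 100 nearest measured genes on each side of ERR. Of these 200 genes 28 (14%) were called, against 1513 of 8663 others (17.5%), an odds ratio of 0.769 (95% interval 0.495 to 1.16, Fisher's exact p = 0.22). This argues against an excess of calls among the genes close to ERR. The test cannot speak to variants farther along the chromosome, whose genes were counted among the others, or to linked variants that act on genes elsewhere. A difference in strain background elsewhere in the genome cannot be told apart from the mutation, since mutants and wild type came from different stocks. That background could contribute to any of the calls, 16.3% of the tested probe sets.

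Other splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 1834 calls and the highest other split 1, and 1 of 10 splits gave as many calls as the real one, which is the real one itself. Every other split mixes the genotypes, so their difference adds to the spread within groups and removes calls. The contrast does not tell how many calls a comparison without a difference would give. For lists past camera with the preset correlation the real split gave 8 and the highest other split 10, and 3 of 10 splits gave at least as many, the real one included. Each of those splits mixes the genotypes unevenly, so part of their difference stays in it and can carry lists past the threshold. Their list counts therefore do not tell how many lists would pass without a difference. With an estimated correlation 0 of 25 lists passed, which is not a measure of correlation alone, as described above. Neither result settles whether the preset correlation holds. The camera p values with it are therefore not used as evidence that a list moved with genotype, and the lists rest on their single-gene calls.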
